A study of Mus musculus with 36 samples.

How the data were processed

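RNA of hypothalamus, cortex and brainstem from male mice was measured by stranded poly(A) RNA sequencing in 36 libraries, 3 for each of 4 genotypes in each of 3 tissues. The genotypes were ataxin-3 transgenic, wild type of that line, Hcrt knockout and wild type of that line, each taken from the sample labels. The authors deposited 1 table per library of raw counts per Ensembl gene, not normalized. Per the submitters' processing notes, reads were trimmed with cutadapt 1.2.1, aligned with TopHat2 2.0.9 to GRCm38 and counted with HTSeq 0.5.4p3. The strand setting of the counting, its overlap mode and the annotation release are not given in the sources used here. A stranded library counted without strand cannot separate a gene from its antisense partner, so the levels of all overlapping genes named below are uncertain.

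Each table held 38924 genes and 5 special lines for reads that were not assigned. The special lines held 24.7% to 42% of a library's counted total and were left out of library sizes and tests. Reads without a feature made up 6.05% to 7.25% in hypothalamus, 10.6% to 13.9% in cortex and 6.38% to 15.2% in brainstem. Reads aligned to more than 1 place made up 16% to 26.4%, and ambiguous reads 0.404% to 0.627%. Genes that share reads with near-identical copies lose such reads, so the globin genes and Gm42418 are less certain in level than single-copy genes. Gene symbols and positions came from the GENCODE M21 annotation of GRCm38, the build of the counts, and 37607 of the 38924 identifiers had both.

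Gene counts per library ran from 21915540 to 47057537. A count of 0 allows up to 3 counts, and this limit covers counting error only, since reads without molecular identifiers are not independent molecules. The biological coefficient of variation was 18% in hypothalamus, 7.35% in cortex and 9.03% in brainstem.

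Differences were tested in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16 (glmQLFit with robust estimation, glmQLFTest) on the deposited counts, with TMM factors and the default expression filter by group. Every adjusted p for a gene is from this test with Benjamini-Hochberg adjustment, unless another tool is named, and the threshold was 0.05 with no minimum fold. The 12 libraries of a tissue entered 1 fit, so that the 4 groups shared an estimate of the spread. The filter left 16738 genes in hypothalamus, 16479 in cortex and 16493 in brainstem. The contrasts were each model against its own wild type, the difference of those effects, and the wild types against each other. The difference between regions was tested in a fit of all 36 libraries. Standard errors of log2 fold changes were derived from the test, as the absolute log2 fold change over the square root of its F statistic. They are approximate, least certain at very low counts.

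A set of 32 gene lists covering regions, cell types and pathways was tested with camera of limma 3.58.1 on voom log2 CPM (prior count 2, preset correlation 0.01), adjusted over the lists with at least 3 tested genes. Beside it stand camera with an estimated correlation and fry, which tests whether the genes of a list move on balance to the same side. With an estimated correlation the calls that held were oligodendrocyte and hypocretin neuron genes between the cortical wild types and blood genes in knockout brainstem, and of these 3 only the last had a fry adjusted p under 0.05 (0.0256, against 0.0549 for each of the others). Lists of genes of the sleep, clock and neuropeptide fields were written from general knowledge and not chosen on these samples. The list genes Kiss1, Slc18a3 and Lhb had no line in the tables and were not used here. Calls shared by the models were counted. Calls within 10 Mb of Hcrt, other than Hcrt, were tested with a one-sided Fisher's exact test, adjusted over 9 tests.

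The genes named were set by a rule. In each comparison these were genes past the threshold whose 3 libraries in the first group all lay on the same side of the 3 in the second, up to 12 with the largest change in each direction. Where fewer than 10 genes passed, the 5 with the smallest p in each direction were named as not past the threshold. Hcrt, Atxn3, Hcrtr1, Hcrtr2 and the 10 hypocretin neuron genes were named always, and up to 4 members with the smallest p for each list discussed. Predicted genes, unnamed identifiers and pseudogenes were named only if among the 3 largest changes. Hbb-bs in brainstem, Pmch in cortex and genes of other tissues such as Omp, Bpifa1, Slc17a7 and Gm42418 were named after their values were seen. Some genes that the rule would name are not reported here. The groups, tests, lists, naming rule and most alternatives were fixed before the data were examined.

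The alternatives were DESeq2 1.42.0, relative log expression factors in edgeR, no filter on low counts, a filter of CPM over 1 in at least 3 libraries, only the groups compared, a replicate block, voom with quality weights and leaving out each library in turn. For the lists they were an estimated correlation, the block and the quality weights, and for the neighbourhood of Hcrt windows of 5 and 20 Mb. Chosen after seeing the data were leaving out 4 hypothalamus libraries with pituitary or nasal transcripts (transgenic 1, its wild types 1 and 3, knockout line wild type 3), also for the correlation of the models' fold changes, leaving a cortex library out of the difference between regions for Hcrt, and covariates for pituitary, striatum, cerebellum and blood genes. A covariate for sex was planned and not applicable, since all libraries carried male transcripts. Without those 4 hypothalamus libraries the ataxin-3 line wild type held 1 library. No library was left out of the results given first.

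The count test was tested on simulated data with the real means, spreads and library sizes, in which 50 genes were changed by each of 4 known folds, and the astrocyte list by 1.25 times in the transgenic line. Changed genes that belonged to that list were not counted, which left 49 for 1.5 and 4 times in transgenic brainstem. In transgenic hypothalamus, with 16625 genes, it recovered 4%, 30%, 52% and 94% of genes changed by 1.25, 1.5, 2 and 4 times, and in knockout hypothalamus 2%, 42%, 66% and 90%. In transgenic cortex, with 16376 genes, it recovered 34%, 78%, 82% and 94%, and in knockout cortex 30%, 68%, 88% and 94%. In transgenic brainstem, with 16379 genes, it recovered 32%, 63.3%, 80% and 89.8%, and in knockout brainstem 24%, 80%, 84% and 100%. False calls were 7 of 97, 2 of 102, 9 of 158, 11 of 151, 7 of 141 and 8 of 152 in the same order. The real comparisons called 1, 2, 0, 13, 1 and 12 genes in that order. More calls make the adjusted threshold easier to reach, so the recovered shares can overstate recovery in the real data. Each gene was drawn independently around its mean over the tissue's libraries. The simulation thus held no shifts shared by many genes, such as transcripts of other tissues in single libraries, and does not measure recovery in their presence. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.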

Results

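Polyadenylated RNA was sequenced from hypothalamus, cortex and brainstem of mice of 4 genotypes, with 3 libraries per genotype and tissue and 36 libraries in all. Hypocretin (orexin) is a neuropeptide made by neurons of the lateral hypothalamus, and its loss gives mice a narcolepsy-like sleep disorder. In the ataxin-3 transgenic line a toxic ataxin-3 fragment kills the hypocretin neurons themselves. In the Hcrt knockout the peptide gene is disrupted. Each model was compared with wild-type mice of its own line, so no control library was shared, and the design sets loss of the gene against loss of the cells. Counts assigned to genes totalled 26146840 to 47057537 per library in hypothalamus, 23860166 to 46001354 in cortex and 21915540 to 42105559 in brainstem. Levels below are CPM, counts relative to library size scaled by TMM factors unless given as unscaled, printed as mean ± SD of 3 libraries, and changes are log2 fold changes with their standard errors (SE).

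Tissue identity held in every library. The cortex marker list had a mean log2 CPM of 6.86 to 7.01 in cortex libraries and at most 3.6 elsewhere. The hypothalamus list lay at 5.37 to 5.89 in hypothalamus and at most -0.2 elsewhere, and the brainstem list at 3.7 to 4.02 in brainstem and at most -1.95 elsewhere. Xist, the female-specific RNA, did not exceed 0.2 unscaled CPM, and the Y-linked Ddx3y was at least 62.9, so the libraries carried male transcripts. Pairs of libraries from the same group differed by more than sampling noise, with a chi-square per degree of freedom of 2.46 to 345 over the 36 such pairs, so no library was a copy of another in its group. Nothing in the labels says that the 3 libraries of a group are separate animals, so the p-values measure the spread between these samples.

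Hcrt, the gene both models are built on, encodes prepro-hypocretin and lies on the minus strand of chromosome 11 at 100761069 to 100762931 in GRCm38 (identifier ENSMUSG00000045471). In hypothalamus it fell from 169 ± 54.3 CPM in the ataxin-3 line wild type to 2.43 ± 0.163 CPM in the transgenic mice (n = 3 each), a log2 fold change of -6.12 (SE 0.30) with an edgeR adjusted p of 9.5e-06. In the knockout it fell from 67 ± 17.4 to 1.13 ± 0.095 CPM, a log2 fold change of -5.90 (SE 0.31) with an edgeR adjusted p of 2.3e-05. The raw counts were 91, 63 and 122 in the transgenic hypothalami against 5244, 3296 and 7126 in their wild types, and 34, 39 and 34 in the knockouts against 3192, 2000 and 2266. All 6 affected libraries lay below all 6 wild-type libraries. The difference between the 2 models' effects was -0.22 (SE 0.41, edgeR adjusted p = 0.98). With only the groups compared in the fit the transgenic call was lost at an adjusted p of 0.12, and with limma voom quality weights the knockout call was lost at 0.16, while the fold changes were -6.12 and -5.88.

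**Figure D1:**
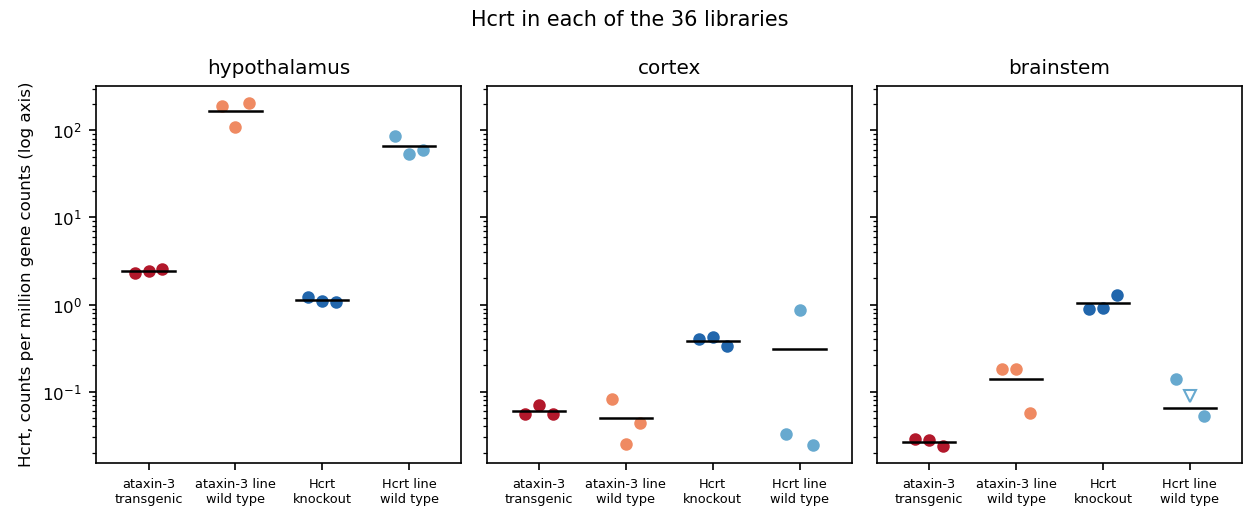
Hcrt unscaled CPM (log axis) in each of the 36 libraries, by tissue and genotype. Points are libraries, black lines are group means, and the open triangle is a library with 0 counts drawn at the upper limit that 3 counts would give; hypothalamus falls from 53.9 or more in wild types to 2.59 or less in both models, and knockout brainstem lies above the other brainstem groups.

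Outside the hypothalamus Hcrt was near the limit of detection in most libraries. Brainstem counts were 1, 1 and 1 in transgenic mice, 5, 4 and 2 in their wild types and 5, 0 and 2 in the knockout line wild types, where the 0 allows up to 0.09 unscaled CPM. In knockout brainstem the counts were 29, 27 and 42. This was a rise from 0.0636 ± 0.070 to 1.01 ± 0.22 CPM, a log2 fold change of 3.91 (SE 0.49, edgeR adjusted p = 0.0017, n = 3 each). In the transgenic brainstem the change was -2.23 (SE 0.88, edgeR adjusted p = 0.55). Cortex counts were 2, 2 and 2 in transgenic mice, 3, 1 and 2 in their wild types, and 17, 10 and 9 in knockouts against 1, 30 and 1 in their wild types. The cortical knockout change was 0.33 (SE 0.78, edgeR adjusted p = 1), because knockout line wild type library 2 alone held 0.881 CPM, and without that library it was 3.63 (edgeR adjusted p = 0.037). That library also held 1.7 CPM of Pmch, the melanin-concentrating hormone gene of neighbouring hypothalamic neurons. The test of the difference between regions, over all 36 libraries, gave a knockout effect on Hcrt in hypothalamus minus cortex of -6.24 (edgeR adjusted p = 0.0026), or -9.53 (8.4e-08) without that cortex library, a run chosen after seeing the data, and in hypothalamus minus brainstem of -9.81 (edgeR adjusted p = 2.4e-08).

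The mouse Atxn3 gene and both hypocretin receptor genes did not pass the threshold in either model in any tissue. Atxn3, a deubiquitinase gene whose human copy carries the repeat of a spinocerebellar ataxia, stood at a log2 fold change of 0.06 (SE 0.11), 0.05 (SE 0.07) and -0.06 (SE 0.07) in transgenic hypothalamus, cortex and brainstem. In knockouts it stood at -0.12, 0.04 and 0.05. Hcrtr1 stood at -0.12, 0.08 and 0.02 in the transgenic line and at 0.15, -0.06 and -0.04 in the knockout. Hcrtr2 stood at 0.11, 0.10 and -0.06 in the transgenic line and at 0.23, 0.12 and 0.03 in the knockout. In simulated data with known changes a 2-fold change was recovered for 52% of genes in transgenic hypothalamus and 66% in knockout hypothalamus. In both cortex comparisons and both brainstem comparisons it was 80% or more, so small changes of single genes in hypothalamus were the least visible. The simulated hypothalamus comparisons called 97 and 102 genes, and the real ones 1 and 2. More calls make the adjusted threshold easier to reach, so these shares can overstate what was visible in the real data. The simulated genes were also drawn independently, without the transcripts of other tissues that single real libraries held.

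The transgenic hypothalamus comparison asks what else disappears when hypocretin neurons die. The neuropeptide gene Qrfp, which is active in lateral hypothalamic neurons, had 1.84 ± 0.35 CPM in transgenic mice against 4.18 ± 0.85 in wild types (-1.18, SE 0.21). It did not pass over all genes (edgeR adjusted p = 0.42) and passed adjusted over the list alone (0.001). It belonged to a list of 10 genes known from hypocretin neurons, of which 8 lay lower and 2 higher in transgenic hypothalamus. These included Dlk1 (-0.48, SE 0.17), the granule protein gene Scg2 (-0.38, SE 0.13), the LIM homeobox gene Lhx9 (-0.78, SE 0.35) and Igfbp3 (-0.28, SE 0.18). Prodynorphin (Pdyn, -0.07), the vesicular glutamate transporter Slc17a6 (-0.12), Nptx2 (-0.03) and galanin (Gal, 0.19) moved less. Ebf2 stood at 2.25 (SE 0.98) because of transgenic library 1 alone. The list as a group lay lower in limma camera (adjusted p = 0.000113), with an adjusted p = 0.0636 with an estimated correlation. None of the 10 passed over all genes and 1, Qrfp, passed adjusted over the list alone. DESeq2 called Qrfp over all genes, with an adjusted p of 0.0076 and a log2 fold change of -1.18.

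In the knockout hypothalamus the same 10 genes did not move together. Qrfp stood at 0.22 (SE 0.20), Dlk1 at -0.18, Scg2 at 0.07, Lhx9 at 0.11, Igfbp3 at -0.09, Gal at 0.29, Pdyn at 0.16, Slc17a6 at 0.07, Nptx2 at -0.08 and Ebf2 at 0.14. The list's camera test gave an adjusted p of 0.614. The 2 models differed for this list (camera adjusted p = 0.000741, and adjusted p = 0.118 with an estimated correlation). For Qrfp the difference between the models was -1.39 (SE 0.29), which did not pass over all genes (edgeR adjusted p = 0.98) and passed adjusted over the list alone (0.0038).

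**Figure D2:**
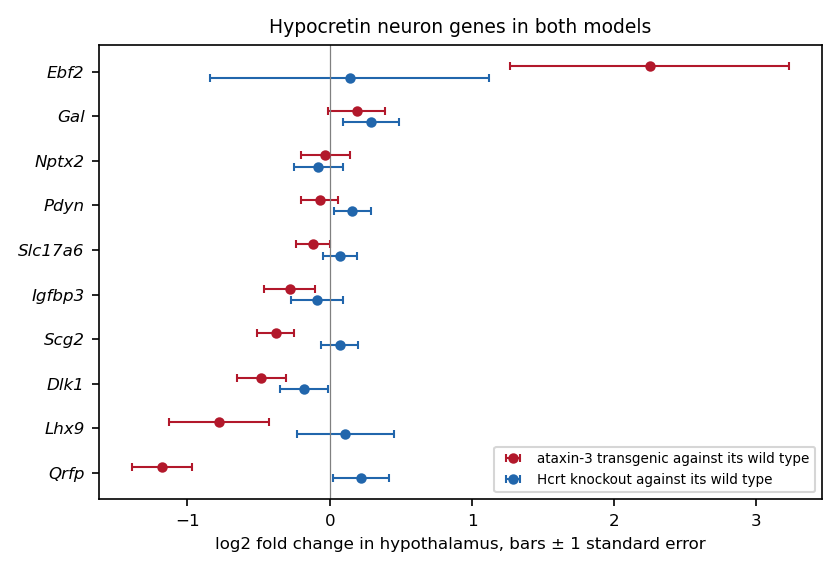
Log2 fold changes of the 10 hypocretin neuron genes in hypothalamus, in the ataxin-3 transgenic and Hcrt knockout comparisons, with standard errors as bars. Qrfp lies at -1.18 in the transgenic comparison and at 0.22 in the knockout.

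Apart from Hcrt, the transgenic hypothalamus had no gene past the threshold: edgeR called 1 gene of 16738 tested, 697 genes had an unadjusted p under 0.05 where 837 were expected by chance, DESeq2 called 7 genes and voom with quality weights 3. The genes with the smallest p that did not pass included Prm1, the sperm protamine gene, with 23, 22 and 38 counts in transgenic hypothalami and 0 in all 6 wild-type hypothalami (edgeR adjusted p = 0.051, and 0.021 without a filter on low counts). DESeq2 called Prm1 with an adjusted p of 0.0076 and voom with quality weights with 1.5e-06. Cenpc1, a centromere protein gene on chromosome 5, had 58.9 ± 2.83 against 38.9 ± 2.26 CPM (0.60, edgeR adjusted p = 0.13), and was called by DESeq2 (adjusted p = 3e-06) and voom with quality weights (adjusted p = 0.0086). The pseudogene Gm9770 had 0.569 ± 0.068 against 0.0752 ± 0.049 CPM. Id4, an inhibitor of DNA binding, stood at 0.38 and BC051019 at 1.10. On the lower side stood Mirg at -0.56, the potassium channel subunit Kcng4 at -0.77 and the cytokine-signalling inhibitor Cish at -0.52, each with an edgeR adjusted p of 0.98 or 1. DESeq2 called Id4 and Mirg (adjusted p = 0.012 and 0.032).

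Several groups of cell type markers moved in transgenic hypothalamus along with tissue that is not hypothalamus. Meningeal and fibroblast genes lay higher for 12 of 12 members (camera adjusted p = 2.49e-11, and adjusted p = 0.31 with an estimated correlation), led by Col1a1 (4.08), Col3a1 (2.26) and Lum (2.07). All 3 changed sign when the libraries with pituitary or nasal transcripts were left out. That run leaves 1 wild-type library in this comparison, so it cannot show which libraries carry the change. Transgenic library 1 also carried nasal epithelium transcripts, with 797 CPM of Bpifa1 and 653 CPM of the olfactory marker Omp. Pituitary genes lay lower for 9 of 9 members (camera adjusted p = 9.56e-06, and adjusted p = 0.38 with an estimated correlation), because growth hormone (Gh) stood at 23700 and 12400 CPM in wild-type libraries 1 and 3. Knockout line wild type library 3 held 17400 CPM of Gh, and no other hypothalamus library exceeded 24.3. Ependymal and tanycyte genes lay higher for 10 of 10 members (camera adjusted p = 9.56e-06, and adjusted p = 0.31 with an estimated correlation). The ciliary genes Foxj1 (0.49, SE 0.16) and Ccdc153 (0.54, SE 0.18) passed adjusted over the list alone (0.049 each), in a fit that includes transgenic library 1 with its nasal transcripts. Thalamus genes lay lower (camera adjusted p = 0.0013), while choroid plexus, microglia and oligodendrocyte precursor genes (0.00851 each) and striatum genes (0.0484) lay higher. Each of these 5 was lost with an estimated correlation, with an adjusted p = 0.38, 0.38, 0.641, 0.38 and 0.65 in that order. Without the 4 libraries with pituitary or nasal transcripts, with 1 wild-type library left, thalamus genes lay higher instead. The other lists of this paragraph kept their direction there. No member of any of these lists passed over all genes in edgeR, and DESeq2 called Gh (-9.57, adjusted p = 0.023).

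The knockout hypothalamus comparison asks what changes when the peptide is lost and the neurons are not targeted. Besides Hcrt, edgeR called 1 gene of 16738. Ghdc, a gene of the GH3 domain family that starts next to Hcrt (chromosome 11, 100766032 to 100770957), fell from 10.1 ± 0.56 to 5.53 ± 0.58 CPM (-0.87, SE 0.10, adjusted p = 0.019). That call was lost in 9 of 15 alternatives, with an adjusted p of 0.74 without the 4 libraries that held pituitary or nasal transcripts and of up to 0.88, with only the groups compared. Unadjusted p-values under 0.05 numbered 651 where 837 were expected by chance. DESeq2 called 10 genes, among them Fkbp10, Asb16, Stat5a, Arhgap27 and the antisense transcript A830036E02Rik (adjusted p = 2e-04, 0.0011, 0.011, 0.026 and 0.0021). Most of the genes next in order of p also lay on chromosome 11. The collagen chaperone Fkbp10 stood at -0.60 (edgeR adjusted p = 0.26), the transcription factor Stat5a at -0.87 (0.64) and Arhgap27 at -0.39 (0.81). Asb16 stood at 0.66 (0.31), gamma-tubulin Tubg1 at 0.36, Acbd4 at 0.43 and the antisense transcript Gm11940 at 2.46 (0.81 each). Plin4, a lipid droplet coat gene on chromosome 17, stood at 0.71 (0.81).

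Among the gene groups, immediate early genes lay lower in knockout hypothalamus for 21 of 23 members (camera adjusted p = 6.72e-06, and adjusted p = 0.564 with an estimated correlation). The activity-dependent genes Arc (-1.02, SE 0.36), Egr1 (-0.91, SE 0.37), Egr2 (-1.29, SE 0.47) and Egr3 (-1.39, SE 0.55) led the list, and none passed over all genes or adjusted over the list alone. Cortex markers moved the same way for 13 of 14 members (camera adjusted p = 0.00869, and adjusted p = 0.564 with an estimated correlation). The cortical glutamate transporter Slc17a7 stood at 127 and 94 CPM in wild-type libraries 1 and 3 and was called by DESeq2 (-5.31, adjusted p = 0.034), and Arc varied widely in that group (28.3 ± 18 CPM, against 13.9 ± 2.3 in knockouts). Blood genes lay lower for 7 of 7 members (camera adjusted p = 0.000128, and adjusted p = 0.564 with an estimated correlation), among them the globin genes Hbb-bt (-0.67) and Hbb-bs (-0.52). Endoplasmic reticulum stress and heat shock genes lay higher for 17 of 20 members (0.00282), with the chaperone Hspa8 at 0.14, and serotonergic genes for 8 of 9 (0.00869), with Ddc at 0.38 (SE 0.13). Cholinergic genes (0.00869), oligodendrocyte genes (0.0411) and hypothalamic neuropeptide genes (0.0462) also lay higher. These 5 camera calls were lost with an estimated correlation, with an adjusted p = 0.672, 0.564, 0.564, 0.922 and 0.875 in that order. Pituitary genes lay lower for 9 of 9 members without passing camera (adjusted p = 0.459), and DESeq2 called Gh (-8.78, adjusted p = 0.049).

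In cortex the transgenic comparison gave no called gene in edgeR (0 of 16479). There were 839 unadjusted p-values under 0.05 where 824 were expected, DESeq2 called 2 genes and voom with quality weights 2. Cenpc1 again had the smallest p, with 36.4 ± 3.61 against 26.5 ± 0.52 CPM (0.46, edgeR adjusted p = 0.75). It was followed by the neurotrophin gene Ntf3 (0.88), the ganglioside synthase gene B4galnt1 (-0.36), Asb18 (-1.85), Lyzl4 (-0.75), the organic anion transporter Slc22a6 (0.42) and Gsto1 (0.28), each at the same adjusted p. DESeq2 called Cenpc1 and B4galnt1 (adjusted p = 0.011 each), as did voom with quality weights (0.0013 and 0.0038) and edgeR without transgenic library 1 (adjusted p = 0.0018 each), and edgeR without a filter on low counts called Cenpc1 (0.038). Of the hypocretin neuron genes in cortex, Dlk1 stood at 0.00, Scg2 at -0.01, Slc17a6 at 0.00, Pdyn at 0.02, Nptx2 at -0.10, Igfbp3 at 0.08, Lhx9 at 0.34 and Ebf2 at -0.42, and none passed. Meningeal genes lay higher for 12 of 12 members (camera adjusted p = 0.0112, and adjusted p = 0.946 with an estimated correlation), with Dcn at 0.35 and Ptgds at 0.33, neither of which passed.

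In knockout cortex 13 genes passed, 4 higher and 9 lower, and 12 of them lay on chromosome 11 near Hcrt. Kcnh4, a voltage-gated potassium channel gene directly beside Hcrt (100740376 to 100759942), fell from 37.1 ± 1.57 to 14.0 ± 1.87 CPM (-1.40, SE 0.08, edgeR adjusted p = 3.2e-07). Ghdc on the other side fell from 5.93 ± 0.33 to 2.81 ± 0.15 CPM (-1.07, SE 0.09, edgeR adjusted p = 5.1e-05). The largest fall was that of the antisense transcript A830036E02Rik, from 111 ± 6.86 to 1.48 ± 0.048 CPM (-6.22, SE 0.10, edgeR adjusted p = 2.9e-15). The keratin gene Krt12, which it overlaps by 5304 bases on the other strand, fell from 13.3 ± 0.48 to 3.20 ± 0.22 CPM (-2.06). Without the strand setting of the counting it is not known whether their reads were kept apart. Stac2 and Plxdc1 also fell (-0.47 each, edgeR adjusted p = 0.001 and 0.00083). The atrial light chain gene Myl4 fell from 24.7 ± 3.93 to 10.6 ± 2.38 CPM (-1.19), and the noncoding C130046K22Rik fell too (-3). Gm11940 rose by 1.70, the homeobox gene Meox1 by 2.08, Arhgap27os3, antisense to Arhgap27, by 2.61, and Adam11 by 0.27 (205 ± 5.04 against 170 ± 5.81 CPM). On the other strand Gm11940 overlaps Krt10 by 558 bases, Meox1 Gm11551 by 4970, Arhgap27os3 Arhgap27 by 5372 and Myl4 Gm22000 by 7740. All these overlaps are of whole gene spans, introns included. Whether the reads of these pairs were mixed is not known either. Adam33 on chromosome 2 was the exception, falling from 19.9 ± 1.47 to 13.8 ± 0.70 CPM (-0.53, SE 0.09, edgeR adjusted p = 0.032). Adam11, Adam33 and Myl4 lost their calls in 9, 8 and 10 of 14 alternatives and Meox1, Arhgap27os3 and C130046K22Rik in 8, 7 and 5 of 13. The count of 13 was 7 to 8 without any 1 library of the knockout line and 5 with the striatum genes as a covariate, chosen after seeing the data, against 22 in DESeq2, 26 with only the groups compared and 35 in voom with quality weights. The striatum list did not overlap between knockouts (3.94 to 4.22 mean log2 CPM) and wild types (3.01 to 3.92). With it as a covariate all 13 genes kept their direction while the standard errors grew by a median factor of 1.29, as for Stac2 (-0.46, SE 0.07) and Adam33 (-0.39, SE 0.1).

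Of the hypocretin neuron genes in knockout cortex, Pdyn stood at 0.21 (SE 0.08), Lhx9 at 0.93, Dlk1 at 0.09, Nptx2 at 0.07, Slc17a6 at -0.01, Ebf2 at -0.04, Scg2 at -0.09 and Igfbp3 at -0.12, and none passed. Gene groups there moved together with markers of striatum. Striatal genes lay higher for 12 of 12 members (camera adjusted p = 4.36e-18, and adjusted p = 0.249 with an estimated correlation), with the adenosine receptor gene Adora2a at 0.78 and Sh3rf2 at 0.79, neither of which passed. Blood genes lay lower for 5 of 5 members (camera adjusted p = 9.42e-07, and adjusted p = 0.249 with an estimated correlation), and Hbb-bt (-0.52), Hbb-bs (-0.48), Alas2 (-0.44) and Hba-a2 (-0.38) passed adjusted over the list alone (0.039 to 0.046). With only the groups compared Hbb-bs passed over all genes (edgeR adjusted p = 0.0045). Oligodendrocyte genes lay lower for 12 of 12 members (camera adjusted p = 4.78e-06, and adjusted p = 0.366 with an estimated correlation), with Opalin at -0.27 and Mog at -0.13. Sleep loss responsive genes lay higher for 15 of 16 (camera adjusted p = 6.8e-05, and adjusted p = 0.249 with an estimated correlation). Among them Fkbp5, a glucocorticoid-induced co-chaperone gene, had 43.3 ± 0.84 against 35.9 ± 1.2 CPM (0.27, SE 0.05) and passed adjusted over the list alone (0.0029), and Hspa5 stood at 0.17. DESeq2 and voom with quality weights called Fkbp5 over all genes (adjusted p = 0.02 and 0.011). Immediate early genes (camera adjusted p = 0.000422), cholinergic genes (0.0177) and clock genes (0.0183) lay higher and meningeal genes (0.0128) lower. Their adjusted p = 0.671, 0.366, 0.59 and 0.671 with an estimated correlation, in that order.

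In transgenic brainstem edgeR called 1 gene of 16493. Cenpc1 rose from 27.1 ± 2.86 to 40.1 ± 0.65 CPM (0.56, SE 0.07, adjusted p = 0.014), and DESeq2 called 18 genes. The Cenpc1 call was lost with only the groups compared (adjusted p = 0.38) and without transgenic library 1, 2 or 3 (0.15, 0.084 and 0.1). Without wild-type library 3 edgeR called 457 genes, Cactin, Myh7b, Etfb, Tmed5, mt-Tm and Orc4 among them (adjusted p = 0.0067 to 0.044). The wild types left there, 1 and 2, stood apart from all other brainstem libraries, with 15900 and 91600 CPM of the ribosomal RNA overlap gene Gm42418 and 10.1% and 15.2% of reads outside any feature. Library 3 had the highest level of the cerebellar granule cell gene Gabra6, 139 CPM against 12.4 and 11.9 in libraries 1 and 2. It also had the lowest Lars2 (236 CPM). Which of these differences goes with the 457 calls was not tested. Unadjusted p-values under 0.05 numbered 1377 where 825 were expected. The genes next in order of p included Cactin (0.34), Gm9770 (4.16), the myosin gene Myh7b (0.56), the electron transfer flavoprotein gene Etfb (0.36), Tmed5 (-0.29), the mitochondrial mt-Tm (-0.93) and the origin recognition gene Orc4 (-0.29), each at an edgeR adjusted p of 0.54. DESeq2 called Cactin, mt-Tm and Gm42418 (adjusted p = 0.042, 0.03 and 1.3e-08). No gene list passed camera. Among the hypocretin neuron genes Pdyn stood at -0.31 (SE 0.14), Gal at -0.22, Igfbp3 at -0.17, Ebf2 at -0.15, Dlk1 at -0.08, Slc17a6 at -0.04, Nptx2 at 0.02, Lhx9 at 0.07 and Scg2 at 0.08, none of them past the threshold.

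In knockout brainstem 12 genes passed, 4 higher and 8 lower, and 11 of them lay on chromosome 11 including Hcrt. Adam11, which encodes a synaptic membrane protein, rose from 94.0 ± 4.79 to 169 ± 16.1 CPM (0.84, SE 0.08, edgeR adjusted p = 0.00062). The Mediator subunit gene Med1 rose from 42.8 ± 1.83 to 55.6 ± 0.48 CPM (0.38, SE 0.06, edgeR adjusted p = 0.014). Gm11940, which overlaps Krt10, rose by 3.17. Ghdc (-0.60), Stac2 (-0.61), the DNA repair gene Rdm1 (-0.80), Igfbp4 (-0.56) and Gm11642 (-1.38) fell, as did C130046K22Rik (-2.37), whose span overlaps Gosr2. Fkbp10, which overlaps Nt5c3b, fell from 6.76 ± 0.69 to 3.81 ± 0.27 CPM (-0.83, SE 0.11, edgeR adjusted p = 0.0026). Ighm, the immunoglobulin heavy chain constant gene on chromosome 12, fell from 59.0 ± 4.39 to 41.4 ± 1.85 CPM (-0.51, SE 0.07, edgeR adjusted p = 0.0026). Med1, Gm11642, Rdm1, Ghdc and Igfbp4 lost their calls in 6, 6, 4, 5 and 10 of 15 alternatives, and with the blood genes as a covariate none of the 12 calls was left. That list did not overlap between knockouts (3.65 to 3.88 mean log2 CPM) and wild types (4.32 to 4.78), so the covariate nearly stood for the genotype. All 12 kept their direction under it while the standard errors grew by a median factor of 2.06, as for Adam11 (0.70, SE 0.18) and Fkbp10 (-1.18, SE 0.20). The count was 6 without knockout library 2 and 7 without wild-type library 2 or 3, against 20 in DESeq2 and 21 with only the groups compared. Among hypocretin neuron genes in this tissue Nptx2 stood at -0.29 (SE 0.09), Gal at -0.31, Igfbp3 at -0.24, Pdyn at -0.16, Ebf2 at -0.13, Dlk1 at -0.12, Scg2 at -0.10, Slc17a6 at -0.07 and Lhx9 at 0.14. As a list they lay lower (camera adjusted p = 0.000936, and adjusted p = 0.052 with an estimated correlation).

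Blood was the clearest gene group in knockout brainstem. The globin gene Hbb-bs had 179 ± 16 CPM in knockouts against 341 ± 49 in their wild types, beside 182 ± 27 and 193 ± 87 in the transgenic and wild-type mice of the other line. All 7 blood genes lay lower (camera adjusted p = 6.85e-14, and adjusted p = 0.0237 with an estimated correlation), and 5 passed adjusted over the list alone, including the heme synthesis gene Alas2 (-1.05), Hbb-bt (-1.13), Hba-a2 (-1.03) and Hba-a1 (-0.99). None passed over all genes in edgeR with all groups in the fit. Alas2, Hbb-bt and Hba-a2 were called by DESeq2 (adjusted p = 5.5e-05, 0.032 and 0.032), by voom with quality weights (0.0082, 0.0076 and 0.014, with Hba-a1 at 0.033) and by edgeR with only the groups compared (0.001, 0.0082 and 0.043, with Hbb-bs at 0.027). Clock genes lay higher for 13 of 19 (camera adjusted p = 0.00887, and adjusted p = 0.382 with an estimated correlation), where the period gene Per2 had 35.5 ± 4.6 against 27.6 ± 0.58 CPM (0.36, SE 0.08, 0.0073 adjusted over the list alone) and Per3 stood at 0.22 (0.028). Without knockout library 3 Per2 passed over all genes (0.46, edgeR adjusted p = 0.02). Choroid plexus genes lay lower for 14 of 14 (0.000936), neuropeptide genes for 13 of 15 (0.000936), endothelial genes for 10 of 12 (0.00195) and microglial genes for 15 of 16 (0.00195). Their adjusted p = 0.575, 0.35, 0.365 and 0.436 with an estimated correlation, in that order. The astrocyte gene Gfap stood at -0.30 (SE 0.08, 0.023 adjusted over the list alone). It lies on the same chromosome as Hcrt and most knockout calls, so a local change cannot be told apart from an astrocyte change. Ependymal genes (0.0236), cholinergic genes (0.0348), interferon genes (0.0362), oligodendrocyte genes (0.0362) and astrocyte genes (0.0443) lay lower and neurotransmission genes (0.0362) higher. All 6 were lost, with an adjusted p = 0.218, 0.481, 0.669, 0.594, 0.287 and 0.335 with an estimated correlation, in that order.

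Across tissues the knockout calls gathered around Hcrt. Besides Hcrt, 19 genes were called in at least 1 tissue of the knockout line, and 17 of them lay on chromosome 11 between 2.84 Mb before and 3.79 Mb after it. Within 10 Mb lay 12 of the 13 cortex calls, where 310 of 16306 placed genes lie (one-sided Fisher's exact test, adjusted p = 2.1e-19), and 10 of the 11 brainstem calls other than Hcrt (325 of 16330 genes, Fisher's exact adjusted p = 4.1e-16). In hypothalamus the 1 call other than Hcrt lay there (Fisher's exact adjusted p = 0.057). No call of the transgenic or wild-type comparisons other than Hcrt did. The share of nearby genes with an unadjusted p under 0.05 in the knockout was 10% against 3.77% elsewhere in hypothalamus, 17.1% against 3.03% in cortex and 13.8% against 2.99% in brainstem. Of 15540 genes tested in every tissue, 8 reached an unadjusted p under 0.01 in the same direction in all 3 tissues of the knockout line, where 0.0039 were expected of independent tissues. They were Stat5a, Stac2, Ghdc, Arhgap27, Asb16, A830036E02Rik, C130046K22Rik and Gm11940, all on chromosome 11. In the transgenic line 1 gene did so, Cenpc1.

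**Figure D3:**
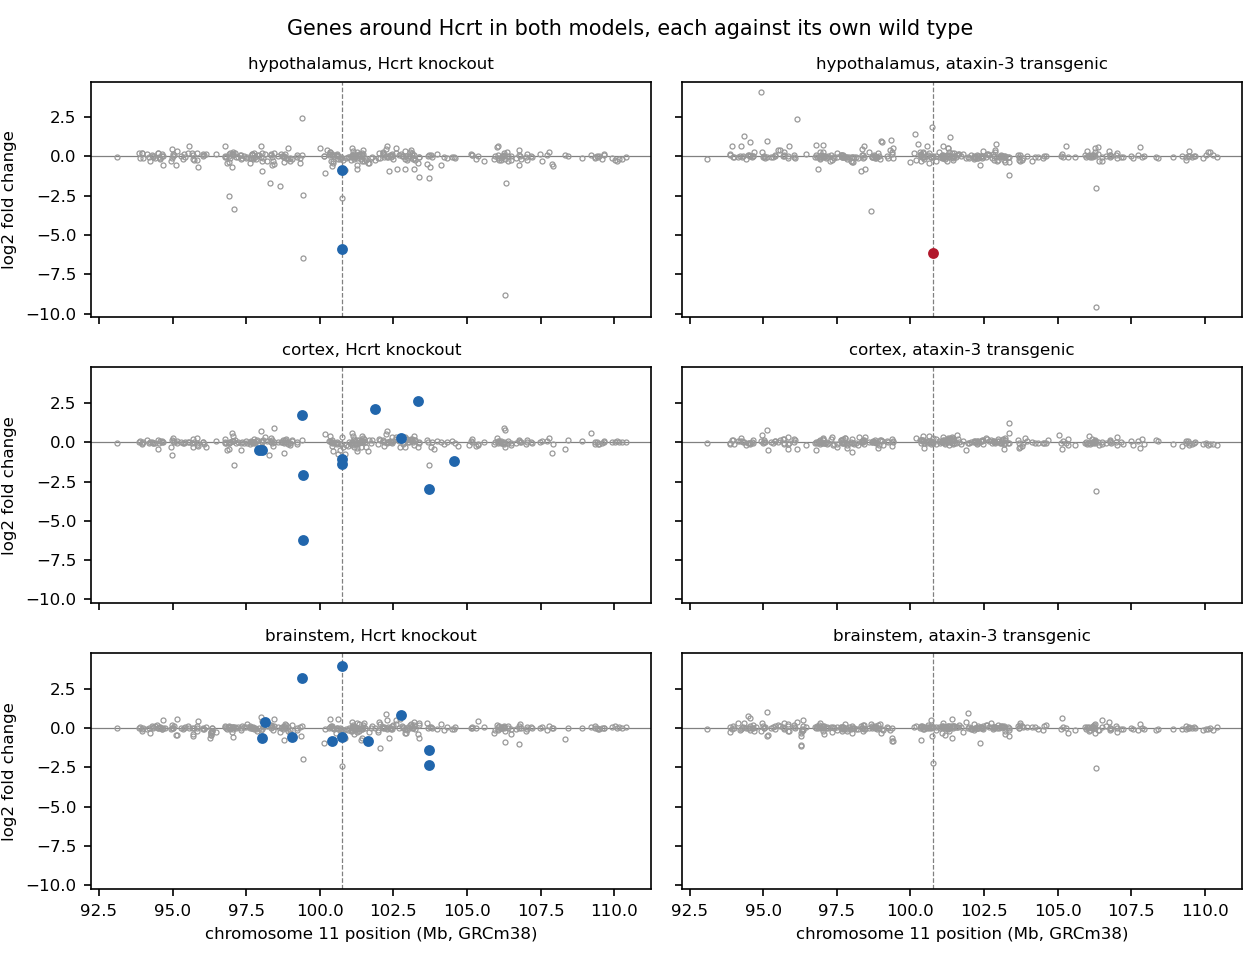
Log2 fold changes of genes within 10 Mb of Hcrt on chromosome 11 (position in Mb, GRCm38) in the knockout and transgenic comparisons of each tissue. The rest of the chromosome is not drawn. Filled points have an edgeR adjusted p under 0.05 and the dashed line is Hcrt; filled points in the knockout lie within 3.79 Mb of it, and the low open point in hypothalamus is Gh.

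The models were then set against each other. In hypothalamus the 1 shared call was Hcrt, lower in both, which is the gene both models are built on. In cortex and brainstem no call was shared: edgeR called 0 and 13 genes in cortex and 1 and 12 in brainstem. Across genes, which are not independent replicates, the fold changes of the 2 models had a Pearson r of 0.32 in hypothalamus, -0.07 in cortex and 0.033 in brainstem, and a Spearman rho of 0.135, 0.001 and 0.026. Wild-type hypothalamus libraries of both lines were among the 4 that held pituitary or nasal transcripts. Without these 4, a choice made after seeing the data, the hypothalamic r was -0.014 and rho 0.117. Every transgenic fold change of that run rests on 1 wild-type library, so it cannot show where the r of 0.32 came from. The direct test of the difference called 4 genes in cortex, all near Hcrt: Ghdc (1.07, edgeR adjusted p = 0.0021), Krt12 (2.14, 1.3e-05), Kcnh4 (1.35, 2.6e-05) and A830036E02Rik (6.24, 4.9e-14). Their transgenic fold changes were 0.01, 0.09, -0.05 and 0.02. In hypothalamus and brainstem it called 0 genes in edgeR, with 378 and 783 unadjusted p-values under 0.05 where 837 and 825 were expected by chance. DESeq2 called 3 and 8 genes. Those were Ghdc, Fkbp10 and Mirg in hypothalamus (adjusted p = 0.00021, 0.00021 and 0.011), and Hcrt, Adam11, Cenpc1, C130046K22Rik, Ghdc, Med1, Stac2 and Gm42418 in brainstem (adjusted p = 1.8e-05 to 0.022). Among lists, immediate early and meningeal genes differed in hypothalamus (camera adjusted p = 1.02e-06 each, and adjusted p = 0.483 each with an estimated correlation), and in cortex striatal genes (1.12e-10, and adjusted p = 0.686 with an estimated correlation) and blood genes (2.18e-05, 0.686).

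The wild types of the 2 lines were compared as a background for these differences. Each wild-type group is also the control of its own model, so this comparison is not independent of the model comparisons. In hypothalamus Hcrt stood higher in the ataxin-3 line (1.34, SE 0.23, 169 ± 54.3 against 67 ± 17.4 CPM) with all 3 libraries above the other 3, and did not pass over all genes (edgeR adjusted p = 1). DESeq2 called it (1.33, adjusted p = 0.00018), as did edgeR without ataxin-3 line library 2 (1.58, adjusted p = 0.015). It stood at 0.60 without the 4 libraries with pituitary or nasal transcripts. That run leaves only library 2 in the ataxin-3 line, the lowest of its group in Hcrt (108 unscaled CPM against 190 and 205). The complement gene C4b had 26.5 ± 2.71 against 41.2 ± 4.39 CPM (-0.64, edgeR adjusted p = 0.24) and was the other gene called by DESeq2 (5e-06), while Tacr3 (0.39), Npas1 (0.69), Amd2 (1.28), BC039966 (0.91), Sap30bpos (-1.38), Ifit3 (-0.46) and the insulin-degrading enzyme gene Ide (-0.58) followed. EdgeR called 0 genes in each tissue. Unadjusted p-values under 0.05 numbered 383, 538 and 2451 in hypothalamus, cortex and brainstem, where 837, 824 and 825 were expected by chance. With that excess in brainstem, 0 calls there does not show that the wild types were alike. DESeq2 called 2, 16 and 286 genes in the same order. In cortex the smallest p belonged to the thyroid hormone deiodinase gene Dio3 (1.19, edgeR adjusted p = 0.26), and Hrk (0.32), Arhgap6 (0.68), the imprinted gene Nnat (0.51), Ide (-0.67) and Igha (-2.76) followed. Voom with quality weights called all 6 (adjusted p = 0.014 to 0.022), and DESeq2 Hrk, Arhgap6, Nnat and Ide (adjusted p = 0.001 to 0.0063). In brainstem Etfb (-0.49), Ano3 (0.37), Aif1 (-1.41), the cold-induced Rbm3 (-0.43), Aspn (0.86), Hook3 (0.36) and Nudt9 (-0.36) had an edgeR adjusted p of 0.15 or 0.16. Without wild-type library 3 of the ataxin-3 line edgeR called 1177 genes in brainstem, these 7 among them (adjusted p = 0.00084 to 0.016). That group then held only the libraries with 15900 and 91600 CPM of Gm42418, and library 3 differed from them in Gabra6 (139 CPM against 12.4 and 11.9). DESeq2 called Etfb, Ano3, Rbm3, Hook3 and Nudt9 (adjusted p = 0.00029 to 0.0043), and edgeR without a filter on low counts called these 5 and Aif1 (0.0082 to 0.021). Atxn3 stood at -0.04, -0.07 and 0.17 in hypothalamus, cortex and brainstem, Hcrtr1 at 0.13, -0.43 and 0.04 and Hcrtr2 at 0.10, -0.17 and 0.26, while Hcrt stood at -2.54 (SE 1.11) in cortex and 1.05 (SE 0.74) in brainstem, and none passed. Of the hypocretin neuron genes in hypothalamus Qrfp stood at -0.40 and Lhx9 at 0.29, and Dlk1 (0.18), Scg2 (0.19), Slc17a6 (0.19), Igfbp3 (0.16), Ebf2 (0.15), Pdyn (0.01), Gal (-0.03) and Nptx2 (-0.08) moved less. In brainstem the 9 that were tested lay between -0.10 (Scg2) and 0.14 (Slc17a6).

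Myelin genes separated the wild types in cortex. This comparison and the knockout comparison share the knockout line wild types, so a change in the same direction in both can come from those libraries. Oligodendrocyte genes in cortex, immediate early genes in hypothalamus and blood genes in brainstem lay lower in both. All 12 oligodendrocyte genes lay lower in the ataxin-3 line (camera adjusted p = 2.69e-22, and adjusted p = 0.0365 with an estimated correlation), and 11 passed adjusted over the list alone. Opalin stood at -0.36 (SE 0.09), Mog at -0.23 (SE 0.06) and Cnp at -0.19 (SE 0.06). The hypocretin neuron genes lay higher for 7 of 8 in the same libraries (camera adjusted p = 0.000131, and adjusted p = 0.0365 with an estimated correlation). Dlk1 (1.2), Slc17a6 (0.21) and Lhx9 (1.36) passed adjusted over the list alone (0.025 each). Hypothalamus markers lay higher for 4 of 4 members there (camera adjusted p = 0.0233, and adjusted p = 0.21 with an estimated correlation), and hippocampus genes for 8 of 10 (0.000151, and adjusted p = 0.21 with an estimated correlation). In brainstem blood genes lay lower in the ataxin-3 line (camera adjusted p = 0.0107, and adjusted p = 0.765 with an estimated correlation), and without ataxin-3 line library 3 Alas2, Hbb-bt, Hbb-bs and Hba-a2 passed over all genes (edgeR adjusted p = 0.0016, 0.0034, 0.02 and 0.031), again with only the libraries high in Gm42418 left in that group. In hypothalamus 15 lists passed camera and none did with an estimated correlation. They were led by immediate early genes (2.85e-06, adjusted p = 0.404 with an estimated correlation) and interferon genes (6.93e-05, 0.404), both lower in the ataxin-3 line, with Ifit3 at -0.46 (0.028 adjusted over the list alone). Cortex markers lay lower there too (camera adjusted p = 0.00246, and adjusted p = 0.404 with an estimated correlation), with a list mean of 2.53 ± 0.25 against 3.06 ± 0.92 log2 CPM and the Slc17a7 of 127 and 94 CPM in knockout line wild types 1 and 3. Immediate early genes had a mean of 3.34 ± 0.1 against 3.67 ± 0.39 log2 CPM in these groups, and of 5.3 to 5.44 in the cortex groups.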

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

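The tests of explanations in this part and the run without a cortex library were all chosen after the results were seen, while the tests of differences between regions and models and the counts of other splits were planned.

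The knockout effect on Hcrt differed between tissues, by -6.24 between hypothalamus and cortex (edgeR adjusted p = 0.0026), or -9.53 (8.4e-08) without wild-type library 2 of cortex, which held 30 Hcrt counts against 1 and 1, and by -9.81 between hypothalamus and brainstem (edgeR adjusted p = 2.4e-08). In cortex the 2 models differed in Ghdc (1.07, edgeR adjusted p = 0.0021), Krt12 (2.14, 1.3e-05), Kcnh4 (1.35, 2.6e-05) and A830036E02Rik (6.24, 4.9e-14), where the knockout falls passed and the transgenic changes lay between -0.05 and 0.09.

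The first pattern is the gathering of knockout calls around Hcrt on chromosome 11. The inserted cassette acting on adjoining genes is argued against as the whole cause, since 3 of the 17 called genes on that chromosome other than Hcrt start within 0.5 Mb of it (Ghdc, Kcnh4 and Fkbp10). Loss of hypocretin signalling in both models is argued against too: over 23 pairs of gene and tissue the transgenic effect, signed by the knockout effect, had a median of -0.02 (SE 0.09) beside a knockout median of 1.07. The pairs are not independent, since genes recur across tissues and share libraries, so this SE is likely too small. The knockout median is over genes called for their knockout effect, which makes it large. Donor-strain sequence left around the modified allele cannot be told apart from other local causes: genes within 10 Mb reached an unadjusted p under 0.05 more often than genes elsewhere in each tissue (largest adjusted one-sided Fisher's exact p = 3e-06), which is the pattern itself. Counts per gene hold no variants, so the strain was not examined. An effect of hypocretin peptide loss on single genes of the region was tested only through the difference between the models. That difference passed in cortex for Ghdc, Krt12, Kcnh4 and A830036E02Rik, whose transgenic changes lay between -0.05 and 0.09. For the other genes such an effect stays open.

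The second pattern is Hcrt reads in knockout brainstem. Hypothalamic tissue carried into the samples is argued against, because knockout brainstem held 90.1% of the knockout hypothalamus level of Hcrt and 0.0806% of that of Pmch, a ratio of 1120. Reads passed over from the wild-type hypothalamus libraries are argued against as well, since they would bring at least 3.37 CPM of Pmch and 0.519 CPM of Avp, where knockout brainstem held 0.468 ± 0.23 and 0.188 ± 0.072 against 0.649 and 0.118 in its wild type, a median excess of 0.041 (SE 0.12) of that needed over these 2 genes; a first set of 3 list markers, 2 of them high in brainstem itself, had decided nothing (-0.054, SE 0.64). Transcription from the modified locus that does not follow Hcrt neurons stays a candidate explanation that was not tested. Knockout hypothalamus held 1.11 times the level of knockout brainstem where the wild types held 1060 times, but that is the pattern itself. Knockout cortex held 0.384 CPM of Hcrt, against 1.12 in knockout hypothalamus. Gene counts do not show which part of Hcrt the reads cover, and the candidate stays open.

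The third pattern is the trio of Prm1, Gm9770 and Cenpc1 in the ataxin-3 line. Male germ cells as the source of Prm1 are argued against, because the germ cell genes Prm2, Tnp1 and Tnp2 had 0 counts in the transgenic hypothalami, where Prm1 had 83. Prm1 sequence within the transgene, transcribed in hypocretin neurons, stays a candidate explanation that these counts do not test. The 1 Prm1 count in the 6 transgenic cortex and brainstem libraries is part of the pattern itself. Transgenic hypothalamus held 2.44 unscaled CPM of Hcrt against 168 in its wild type, so little Hcrt was left beside 0.744 CPM of Prm1. Knockout hypothalamus held 4 Prm1 counts and knockout brainstem 5, which this candidate does not explain. For sequence of another strain around Cenpc1, genes within 5 Mb reached an unadjusted p under 0.05 in 16.7% against 4.16% elsewhere in hypothalamus, 0% against 5.05% in cortex and 4.17% against 8.37% in brainstem, and the smallest one-sided Fisher's exact p was 0.016. A first rule would have ruled this out, since the share lay at or below that elsewhere in 2 of 3 tissues; it was replaced after that outcome was seen by a rule asking for a deficit past the threshold in at least 2 tissues, met in 0, because 0 of 20 cortex genes lies within chance (Fisher's exact p = 0.35), so the explanation cannot be told apart from others and rests on a rule changed late.

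Other splits of the same libraries were counted for each comparison. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The knockout comparisons called 2, 13 and 12 genes in hypothalamus, cortex and brainstem, the highest other split called 0 in each tissue, and the real split was the 1 of 10 with as many. The transgenic comparisons called 1, 0 and 1 genes, against a highest other of 6, 1 and 34, and 2, 10 and 2 of 10 splits gave as many. The wild-type comparisons called 0 genes in each tissue, against a highest other of 98, 0 and 3, so that 10 of 10 splits gave as many. For the difference between the models 60 regroupings were drawn. In cortex 5 of 60 gave at least the real 4 genes (highest other 7), and these 5 were the draws that kept the knockout grouping and with it the knockout effect, so the count says nothing about chance. In hypothalamus and brainstem the real count was 0, which all 60 of 60 regroupings reach, with a highest other of 2 and 307. The splits with 98, 34 and 307 calls point to a structure of the samples that the genotypes do not describe.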

How the results depend on the processing

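The runs without 4 hypothalamus libraries and with tissue covariates were chosen after seeing the data, and all other alternatives were planned. Most values that answer a comparison are counts of genes or lists. A count was scored as kept when it equalled the main count or lay within a set factor of it, whichever genes it held. Hcrt in hypothalamus was scored by direction and side of the threshold, and the neighbourhood tests by side of the threshold. By these scores 216 values were kept, 86 moved, 2 weakened and 1 strengthened. Of the values for named genes, 2821 kept their direction and side of the threshold, 113 passed anew, 103 no longer passed and 40 changed sign. The cause was not tested in any case. DESeq2 called 7, 10, 3 and 2 genes in hypothalamus (transgenic, knockout, difference of the models, wild types), 2, 22, 8 and 16 in cortex and 18, 20, 8 and 286 in brainstem. It called 2 shared genes in hypothalamus, of which 1 was the pituitary gene Gh. Without a filter on low counts edgeR called 2 genes in transgenic hypothalamus, 1 in transgenic cortex, and 5 for the difference and 19 for the wild types in brainstem. With only the groups compared it called 0, 1 and 1 genes in hypothalamus (transgenic, knockout, wild types) with 0 shared, 26 in knockout cortex, 16 between cortical wild types, and 0 and 21 in transgenic and knockout brainstem, and Hcrt stood at -6.12 (adjusted p = 0.12) in transgenic hypothalamus. Voom with quality weights called 3, 1 and 1 genes in hypothalamus (transgenic, knockout, wild types) with 0 shared, and 2, 35, 8 and 25 in cortex, with Hcrt at -5.88 (adjusted p = 0.16) in knockout hypothalamus. With those weights the lists called were 13 for the difference in hypothalamus, 5 and 4 in transgenic and knockout cortex and 7 in knockout brainstem.

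With a replicate block edgeR called 1 gene in knockout hypothalamus, 8 in knockout cortex and 3 between cortical wild types, and camera called 5 lists in transgenic cortex. Deviations of same-numbered libraries had correlations from -0.335 to 0.455. All 3 were above 0 in transgenic hypothalamus (0.055 to 0.324), knockout cortex (0.063 to 0.092) and knockout brainstem (0.083 to 0.337), but in no comparison was every pair above 0.1 or every library closest to its own number. By that rule the numbers were not taken as pairs, and the paired fits are given only here. With an estimated correlation camera called 0 lists in each hypothalamus comparison, in transgenic cortex, in knockout cortex, for the difference in cortex and brainstem and between brainstem wild types, 2 between cortical wild types and 1 in knockout brainstem. In a window of 5 Mb the neighbourhood test in knockout hypothalamus had a Fisher's exact adjusted p of 0.039. Knockout hypothalamus had 1 called gene without the 4 libraries and 1 with the pituitary covariate. The striatum covariate left 5 in knockout cortex. In brainstem the cerebellum covariate gave 2 in the transgenic comparison and 10 for the difference, and the blood covariate 2 and, in the knockout, 0. A sex covariate was not run.

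Leaving out 1 library at a time gave 1 to 1, 1 to 5, 0 to 0 and 0 to 3 genes in hypothalamus, 0 to 3, 7 to 8, 4 to 6 and 0 to 2 in cortex, and 0 to 457, 6 to 11, 0 to 85 and 0 to 1177 in brainstem, where the highest transgenic, difference and wild-type counts came without wild-type library 3 of the ataxin-3 line. Hcrt ran from -6.36 to -5.94 in transgenic and from -6.03 to -5.66 in knockout hypothalamus.

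Over such runs the genes that changed sign in transgenic hypothalamus ran from -0.36 to 2.76 (Ebf2), -0.25 to 0.10 (Nptx2), -0.13 to 0.04 (Pdyn) and -0.19 to 0.07 (Mchr1). In knockout hypothalamus they ran from -0.05 to 0.28 (Ebf2), -0.22 to 0.17 (Igfbp3), -0.14 to 0.34 (Lhx9), -0.20 to 0.00 (Nptx2), -0.01 to 0.14 (Scg2) and -0.05 to 0.18 (Slc17a6), and Hcrt in cortex ran from -0.05 to 0.69 in the transgenic line and from -0.29 to 3.63 in the knockout.

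Genes that changed sign in transgenic hypothalamus were Hcrtr1 under quality weights (0.01), Igfbp3 with the pituitary covariate (0.00), Pdyn without wild-type library 2 (0.04), Nptx2 without transgenic library 2 (0.03) or 3 (0.10) or wild-type library 2 (0.08), and Ebf2 (-0.36) and Mchr1 (0.07) without transgenic library 1. Without the 4 libraries, a run with 1 wild-type library left in this comparison, they were Ebf2 (-0.51), Mchr1 (0.02), Hcrtr2 (-0.03), Agrp (-0.01), Pmch (0.12), Gh (0.50), Col1a1 (-0.18), Col3a1 (-0.12), Lum (-0.11) and Ifitm3 (0.00). In knockout hypothalamus they were Lhx9 under quality weights (-0.10) and without knockout library 1 (-0.12) or wild-type library 2 (-0.14), Scg2 under quality weights (0.00) and without knockout library 1 (-0.01) or wild-type library 1 (0.00), and Igfbp3 without knockout library 2 (0.04), without wild-type library 3 (0.17), without the 4 libraries (0.17) and with the pituitary covariate (0.04). The others there were Nptx2 without knockout library 3 (0.00) or wild-type library 2 (0.00), Slc17a6 without knockout library 3 (-0.04) or wild-type library 1 (-0.05) and Ebf2 without wild-type library 1 (-0.05). In cortex Hcrt turned in the transgenic line without wild-type library 2 (-0.05) and with the striatum covariate (-0.29), and in the knockout without wild-type library 1 (-0.14) or 3 (-0.29), and S100b turned in the knockout with the striatum covariate (0.03). In knockout brainstem Hbb-bt (0.01) and Per3 (-0.03) turned with the blood covariate. Depth limits Hcrt outside the hypothalamus, where most libraries held 5 counts or fewer. The spread between libraries limits hypothalamus, where a change of 1.5 times was recovered for 30% of simulated genes in the transgenic comparison. That share can overstate recovery in the real data, which held fewer calls and whose genes need not vary independently as the simulated ones did.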

Other observations

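The gene lists behind these values were planned, and the tests of genes that moved alike in all tissues and the look at transcripts of other tissues were chosen after the data were seen.

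Clock genes differed between the cortical wild types on both sides. Arntl, the activator of the clock, stood 0.24 higher in the ataxin-3 line and Ciart (-0.31), Dbp (-0.22) and Bhlhe41 (-0.18) lower, and these 4 passed adjusted over the list alone (0.0039, 0.0039, 0.039 and 0.049) without passing over all genes in edgeR with all groups in the fit. DESeq2 and voom with quality weights called Arntl (adjusted p = 0.041 and 0.022), and edgeR with only the groups compared called Ciart (adjusted p = 0.032). In brainstem the cold-inducible RNA-binding genes Rbm3 (-0.43) and Cirbp (-0.35) stood lower in the ataxin-3 line wild type, passing adjusted over the list alone (0.00057 and 0.0013), and so did the microglial gene Aif1 (-1.41, 6e-04). DESeq2 called Rbm3 and Cirbp over all genes (adjusted p = 0.00064 and 0.006), and edgeR without ataxin-3 line library 3 called all 3 (0.0022 to 0.0028), with only that line's libraries 1 and 2 left, which are high in Gm42418 and Lars2. In transgenic brainstem Slc18b1 (-0.32) and Rorb (-0.26) passed adjusted over their lists alone (0.014 and 0.036). In transgenic hypothalamus the interferon-induced genes Ifit1 (0.83) and Ifit3 (0.39) did so as well (0.042 and 0.043), with Moxd1 (0.81, 0.018). The astrocyte gene Gfap lies on chromosome 11, as do Hcrt and most knockout calls, so its change need not be one of astrocytes. It stood at -0.30 in knockout cortex with an edgeR adjusted p of 0.068 (0.00076 adjusted over the list alone) and at -0.30 in knockout brainstem. In cortex it was called by DESeq2 (adjusted p = 0.00049), voom with quality weights (adjusted p = 0.0023) and edgeR without a filter on low counts (adjusted p = 0.032) or with only the groups compared (adjusted p = 0.0089).

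Between the wild types 2 genes reached an unadjusted p under 0.01 in the same direction in all 3 tissues. Ide, the insulin-degrading enzyme gene on chromosome 19, stood at -0.58 in hypothalamus, -0.67 in cortex and -0.45 in brainstem, and G530011O06Rik on chromosome X was the other. Of 15540 genes, 0.0039 were expected of independent tissues.

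Transcripts of neighbouring tissue appeared in single libraries. Hypothalamus libraries of the ataxin-3 line wild type 1 and 3 and of the knockout line wild type 3 held 3560, 2030 and 2630 CPM of prolactin (Prl). Transgenic hypothalamus library 1 held 780 CPM of Bpifb3 and 564 CPM of Scgb1c1, both of nasal epithelium. Hypothalamus library 1 of the knockout line wild type held 31.1 CPM of Eomes and 29.7 CPM of Doc2g, and knockout library 3 held 64.7 CPM of the dopamine transporter gene Slc6a3. The cerebellar granule cell gene Gabra6 ran from 8.6 to 139 CPM across brainstem libraries, and stood at 15.7 and 7.74 CPM in cortex transgenic library 3 and wild-type library 2 of that line. In brainstem wild-type libraries 2 and 1 of the ataxin-3 line Lars2 stood at 8700 and 2090 CPM, with 15.2% and 10.1% of reads outside any feature.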
